A study of Oryza sativa with 6 samples.

How the data were processed

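Total RNA of rice caryopses collected 7 days after flowering was labelled with biotin and hybridized to 6 Affymetrix rice genome arrays, 3 of wild-type Zhonghua11 and 3 of gif1, which the labels call biological repeats. The deposited values are intensity signals on a linear scale, 1 per probe set, made with GCOS 1.4 per the submitters' processing notes. How GCOS corrected background, summarized probes and scaled the arrays is not given in the sources used here. The deposited values themselves show that the mean after trimming 2% at each end is about 500 on every array, and that medians differ. Each column was matched to its sample by the column's own label, and no column was left unmapped (0). For arrays, their number limits the precision, with 6 in all.

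The file held 57381 probe sets, of which 187 control probe sets were left out (the AFFX controls named in the design and also the RPTR reporter probe sets), leaving 57194. Signals were transformed as log2(signal + 17.7), the offset being the 25th percentile of all values, so a fold change is on that scale and is understated for dim probe sets. Probe sets with a mean signal over the 6 arrays of at least 74.1, the median over probe sets, were tested (28597). Of all probe sets, 22436 had 1 gene in the platform annotation, 95 had several and 34850 were not listed, and none was named from a probe set with several. The 22436 gave 17905 genes, of which 2458 have a symbol other than a LOC number. Names and gene order came from the RefSeq gene table of assembly ASM3414082v1, in which all 22436 were found. Since the arrays' own build is not given in the sources used here, no coordinates are printed. Of the tested probe sets 18206 had 1 gene, and these gave 15423 genes. Where a gene has several probe sets, the brightest stood for it. Of the called named genes 14 had another tested probe set, and for 8 of them at least 1 did not pass, though none passed in the other direction (0). These 8 were HSP81-1, OsPM19L1, RAG2, RBCS, RPL27, RPS21, RPS3A and Wx, and for all of them but RAG2 and RBCS no other probe set passed. Of the genes not called, BEI and NSHB1 had others that passed. Probe sets whose identifiers end in _x_at or _s_at, among them those of RBCS, Wx and GluA-1, can also bind transcripts of related genes.

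Differences between gif1 and wild type were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes and an intensity trend in the prior variance, genotype as the only term and Benjamini-Hochberg adjustment over all tested probe sets, at 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry (statmod 1.5.0), adjusted over 15 lists. Technical measures were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 arrays is 0.1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

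The groups, tests, alternatives and gene lists were fixed before the data were examined. The lists had been fixed as locus identifiers and description patterns, and the annotation used here holds neither, so members were found by gene symbol and synonym, with patterns written before any difference between genotypes was seen. The lists tested therefore differ from the planned ones. The 15 lists, with the locus identifiers fixed and then the genes matched by symbol, are starch synthesis (28 and 8), sucrose cleavage and sugar transport (24 and 31), seed storage proteins (23 and 10), endosperm transcription factors (9 and 4), aleurone and embryo markers (11 and 10), photosynthesis (17 and 11), amylases (11 and 5), ER chaperones (9 and 19), heat shock proteins (11 and 26), pathogenesis-related and defence genes (16 and 21), fermentation and hypoxia (8 and 6), cell cycle and DNA replication (10 and 34), ribosomal proteins (0 and 22), cell wall synthesis and loosening (8 and 58), and hormone synthesis and response (12 and 58). The genes named are GIF1, then the 10 largest rises and 10 largest falls among genes past 0.05 whose groups do not overlap, with 1 probe set per gene and none ending in _x_at, and up to 4 members of each list with the smallest p. The 10 rises and 10 falls among genes with a symbol were added after the values were seen, and so were SUS4, FRK1, RAB16C, OSH1, VP1, LEA19, Dhn1, RAB16D, CAB2R, SWEET11, LOC4324064, LOC4326054, Hox19 and the probe sets with no gene listed.

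The fit was tested on simulated data with the real arrays' spread over 28597 probe sets. It recovered 28% of 100 probe sets changed 2-fold, 64% of 100 changed 4-fold and 10 of 20 in a list shifted 2-fold. Of its 108 calls, 6 were false (5.56%). With no change simulated it made 0 calls. On simulated lists of 20 genes, limma's camera found a shifted list (2.85e-42) and not an unshifted one (0.555). The simulated noise was independent between probe sets, so these lists held no correlation between genes. In the real lists the estimated correlation was 0.76 for storage and 0.26 for photosynthesis. The simulation therefore does not test list calls made at the preset correlation of 0.01. It also changed a far smaller share of probe sets than the 11.98% called in the real data. Recovery after Benjamini-Hochberg adjustment depends on that share, so the recovered shares need not hold for the real arrays.

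The alternatives were other offsets, a floor in place of the offset, quantile normalization, median centring, no filter and a stricter one, eBayes without the trend and in its robust form, array weights, the replicate number as a block, leaving out each array in turn, leaving out _x_at and _s_at probe sets, and, for lists, the mean of all probe sets of a gene and an estimated correlation. Scaling to the hybridization spikes was added after the data had been seen. Leaving out an array leaves fewer to test, so a call can be lost through less power though the difference does not shrink. A lost call alone therefore does not show that a difference rests on that array.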

Results

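Transcript levels were measured in rice caryopses, the developing grains, 7 days after flowering on 6 single-colour oligonucleotide arrays. Wild-type Zhonghua11, a japonica cultivar, and the mutant gif1 each gave 3 arrays, 1 per biological repeat. The mutant carries a lesion in GIF1 (GRAIN INCOMPLETE FILLING 1, also OsCIN2), a cell-wall invertase that splits sucrose on its way into the grain. The question put to the arrays was which transcripts differ between the genotypes while the grain fills. Values below compare n = 3 arrays of gif1 with n = 3 of wild type, except where a single array is said to be left out, and a log2 difference is gif1 minus wild type. The median signal over probe sets was 103.6, 83.7 and 95.75 on the wild-type arrays and 67.5, 72.6 and 72.4 on the gif1 arrays, although the trimmed mean was about 500 on all of them. Spearman correlations across probe sets, which are not independent replicates, ran from 0.841 to 0.854 within wild type, from 0.861 to 0.867 within gif1 and from 0.834 to 0.858 between genotypes.

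The GIF1 transcript itself was lower in the mutant. Its probe set read 654.2, 428.6 and 607.7 in wild type and 173.3, 100.9 and 190.4 in gif1. The means were 564 ± 119 (SD, n = 3) and 155 ± 47.5 (SD, n = 3), so GIF1 fell by 1.77 on the log2 scale (SE 0.28, limma adjusted p = 0.00254). Where the probes lie relative to the lesion was not examined, so this value checks the labels only as far as the lesion lowers the transcript.

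Changes in the rest of the transcriptome ran in both directions. Of 28597 probe sets tested, 1709 were higher and 1716 lower in gif1 at a limma adjusted p under 0.05, 11.98% of those tested. A change of at least 2-fold was found for 1280 of them, 553 higher and 727 lower. At the level of genes, with 1 probe set each, 1221 genes rose and 869 fell. The groups did not overlap for 33.4% of the tested probe sets, against 10% by chance with 3 arrays in each group. The balance between rises and falls follows from how the arrays are scaled: with each array centred on its median the counts were 5817 higher and 613 lower (90.5% higher), and with arrays scaled to the hybridization spikes, a choice made after seeing the data, they were 9810 and 463 (95.5% higher). The median log2 difference of the tested probe sets was -0.06 as deposited, 0.28 after median centring and 0.44 with spike scaling, so each difference is relative to that level. Without the intensity trend in limma's variance model, 368 probe sets were higher and 416 lower.

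Several technical measures moved with the genotype. The poly-A control RNAs, which are added to the sample before labelling, were 4.72-fold lower on the gif1 arrays (log2 difference -2.24), and rice ribosomal RNA probe sets were 2.09-fold lower (-1.06). The hybridization controls, added after labelling, were 1.42-fold lower (-0.51), and the median signal was 1.33-fold lower (-0.41). For each of these 4 measures all gif1 arrays lay below all wild-type arrays, with a two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays can give (0.175 after adjustment over 7 measures). The 3'-to-5' ratios, a sign of RNA integrity, overlapped between genotypes for actin (-0.32, exact permutation p = 0.4), GAPDH (-0.10, exact permutation p = 0.2) and cyclophilin (-0.19, exact permutation p = 0.5).

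Among genes taken with their brightest probe set, leaving out overlapping groups and probe sets ending in _x_at, the largest rise belonged to LOC4347994, from 54.0 ± 35.4 to 1456 ± 617 (log2 difference 4.40, SE 0.40). LOC4350752 (3.57), LOC4331323 (3.55), LOC4337342 (3.40), LOC4327281 (3.00), LOC4346594 (2.91), LOC4337901 (2.87) and LOC4339956 (2.85) rose too, as did the expansins EXPB9 (3.02, SE 0.36) and EXPA32 (2.94, SE 0.58), wall-loosening proteins. EXPA32 read 7.90 ± 0.917 in wild type and 183 ± 50.05 in gif1. The largest falls among these genes were those of LOC4339887, from 675 ± 134 to 63.8 ± 31.1 (-3.16, SE 0.34), and LOC4338652 (-3.13, SE 0.53). They were followed by LOC4340064 (-2.90), LOC4326705 (-2.68), LOC9266106 (-2.66), LOC4340512 (-2.62), LOC4346886 (-2.58), LOC4332792 (-2.51), LOC4325776 (-2.47) and LOC4349795 (-2.39). All 20 had limma adjusted p-values under 0.05 and groups that did not overlap. A larger fall, that of LOC4326054 (-4.01, SE 0.99), had overlapping groups and lost its call without wild-type replicate 3 (adjusted p = 0.0726) and without gif1 replicate 2 (0.0569) or 3 (0.0832). The added offset set the size of the difference for EXPA32, LOC4327281 (15.4 in wild type), LOC4338652 (23.6 in gif1), LOC4326705 (17.37 in gif1) and LOC4332792 (40.7 in gif1). Without it they stood at 4.50, 4.03, -4.39, -3.75 and -3.57 (LOC4332792 then not passing, limma adjusted p = 0.0578), and with an offset 4 times as large at 1.67, 1.88, -2.06, -1.64 and -1.67. Leaving out a single array ended the calls of LOC4325776 (adjusted p = 0.0572) and LOC4349795 (0.0520) without wild-type replicate 2, LOC4340512 (0.0545) without wild-type replicate 3, LOC4326705 without wild-type replicate 1 (0.0510) or 2 (0.0636), and LOC4332792 without wild-type replicate 3 (0.0952) or gif1 replicate 1 (0.0617). Over all probe sets the largest fall was larger, from 1128 to 11.6 (-5.37, SE 0.36), in a probe set with no gene listed, and the second-largest rise, from 6.57 to 364 (3.89, SE 0.51), had none listed either. A dimmer probe set of LOC4324064 also fell further (-3.29, SE 0.44), while that gene's brightest probe set differed by -0.07 (SE 0.13).

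Most of these genes have no symbol in the annotation, so the largest changes among genes with one are given as well under the same limits, a choice made after the values were seen. These limits leave out RBCS (2.23) and Hox19 (-1.57, SE 0.41), whose probe sets end in _x_at. Hox19 lost its call without any array but wild-type replicate 2 (adjusted p up to 0.0924), and with quantile normalization (0.0567) and spike scaling (0.0516). Beyond the expansins, the rises were those of NifU1, an iron-sulphur cluster scaffold (2.80, SE 0.22), BHLH172 (2.63), ASMT3 (2.61), the sugar transporter SWEET5 (2.48), PDX12 of vitamin B6 synthesis (2.44), GDCSH, the H protein of glycine decarboxylase (2.10, SE 0.21), the laccase LAC10 (1.99) and mfs1 (1.94). The falls beside GIF1 were those of the protein phosphatases OsPP2C18 (-2.30) and OsPP2C25 (-1.52), the membrane protein OsPM19L1 (-2.17, SE 0.30), the zinc-finger protein OsC3H10 (-2.07), the zinc transporter OsZIP4 (-1.66) and 4 dehydrins, RAB16B (-2.03), rab25 (-2.01), RAB16A (-1.62) and RAB16C (-1.48). OsPP2C18 read 15.3 in gif1, under the offset, and stood at -3.32 without it (limma adjusted p = 0.0581) and at -1.31 with one 4 times as large, and BHLH172 read 19.03 in wild type and stood at 3.46 and 1.65. Leaving out gif1 replicate 1 ended the calls of BHLH172 (adjusted p = 0.0778), SWEET5 (0.0860), PDX12 (0.0562) and OsPP2C18 (0.0599). Leaving out gif1 replicate 2 ended those of BHLH172 (0.0596) and SWEET5 (0.0999), gif1 replicate 3 those of mfs1 (0.0515) and OsPP2C18 (0.0601), and wild-type replicate 2 or 3 that of SWEET5 (0.0680 and 0.0515). A further probe set of OsPM19L1 differed by -0.49 (SE 0.29) and did not pass.

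**Figure D1:**
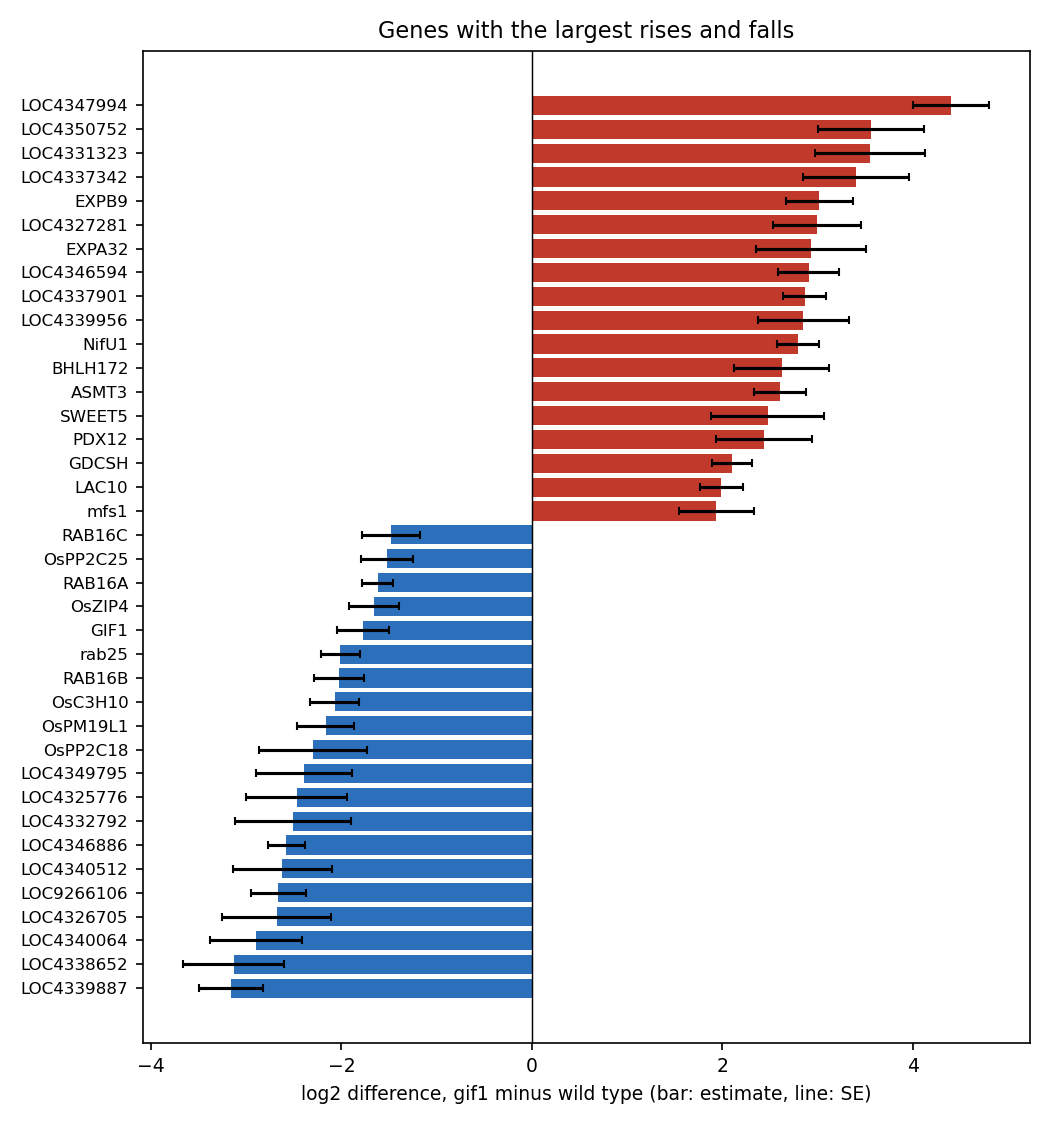
Log2 difference (gif1 minus wild type, n = 3 arrays each) of genes with large rises (red) and falls (blue) past limma's adjusted p of 0.05, with 1 probe set per gene, none ending in _x_at, and groups that did not overlap. Shown together are the 10 largest rises and 10 largest falls among all genes and those among genes with a symbol. The latter were added after the values were seen, so the figure is not a single ranking by size. Bars give the estimate and lines its SE; values run from -3.16 for LOC4339887 to 4.40 for LOC4347994.

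Seed storage protein transcripts, the markers of starchy endosperm, fell together. All 9 measured members passed, 9 of 9 when adjusted over the list alone, with a mean log2 difference of -0.62 (-0.29 with median centring and -0.11 with spike scaling). RAG1, a seed allergenic protein, went from 40917 ± 16350 to 14854 ± 4211 (-1.43, SE 0.26), the glutelins GluA-1 and GluD-1 differed by -0.54 (SE 0.10) and -0.60 (SE 0.11), and RAG2 by -0.64 (SE 0.13). RAG1 kept its call under quantile normalization, median centring and spike scaling (-0.92 with the last), while GluA-1, GluD-1 and RAG2 lost theirs under each of these (-0.03, -0.09 and -0.13 with spike scaling). The camera test against other genes gave adjusted p = 1.98e-07 for the list, and adjusted p = 0.455 with an estimated correlation. Quantile normalization took the mean to -0.19 and ended the call (adjusted p = 0.183). The list is among the brightest on the array, and the 130 other probe sets with 1 gene that were at least as bright had a mean log2 difference of -0.31, with 90% of them lower. Only the brightest probe set of each storage gene was left out of these, and Wx, BEI and RAB16A were among them. Further probe sets of storage genes could be among them too. Starch synthesis genes did not pass as a list (mean -0.16, adjusted p = 0.0687; 0.17 after median centring and 0.34 with spike scaling). Of its 8 measured members, against 28 loci planned, 1 fell and 7 did not pass, and 3 fell when adjusted over the list alone. The member that fell was Wx, granule-bound starch synthase (-0.48, SE 0.10; 0.03 with spike scaling), though its 4 other probe sets did not pass (-0.55 to -0.23) and leaving out gif1 replicate 1 or 3 ended its call (adjusted p = 0.0666 and 0.0546). Branching enzyme BEI (-0.36, SE 0.12; 3 of its 4 other probe sets passed as lower, -0.89 to -0.38), PPDKB (-0.25, SE 0.09) and AGPS2 (-0.20, SE 0.13) did not pass.

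Photosynthesis transcripts, taken as markers of the green pericarp, rose in gif1. Of 10 measured members 9 rose, 9 also when adjusted over the list alone, where 1 further member, CAB2R (-0.25, SE 0.09, adjusted p = 0.106 over all probe sets; 0.26 with spike scaling), counted as lower. The small subunit of Rubisco, RBCS, went from 1550 ± 431 to 7175 ± 1111 (2.23, SE 0.20; 0.86 and -0.46 in its other probe sets, the latter not passing) and Rubisco activase, RCA, from 6919 ± 600 to 18873 ± 3620 (1.43, SE 0.14). The photosystem I subunit PSAH (0.90, SE 0.12) and plastocyanin, PETE (0.78, SE 0.11), rose less. The list's mean log2 difference was 0.86 with camera adjusted p = 3.01e-07, and adjusted p = 0.263 with an estimated correlation. The storage list moved the other way on the same arrays (-0.62), and the poly-A controls lay at -2.24.

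Aleurone and embryo markers were mostly lower. Of 10 measured members 5 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone, with a mean log2 difference of -0.80 (-0.47 with median centring and -0.30 with spike scaling). The dehydrin rab25 went from 15694 ± 6114 to 3701 ± 174 (-2.01, SE 0.20) and RAB16A from 55029 ± 15602 to 17539 ± 1699 (-1.62, SE 0.16). RAB16B (-2.03, SE 0.26), RAB16C (-1.48, SE 0.31) and Emp1, an Em-type late embryogenesis abundant protein (-1.38, SE 0.19), fell as well, whereas OSH1, a homeobox gene of the embryo's shoot meristem, rose (0.93, SE 0.26), a call lost without any single array but wild-type replicate 1 (adjusted p up to 0.142). The abscisic acid response regulator VP1 differed by -0.73 (SE 0.23, limma adjusted p = 0.0636) and did not pass, and neither did LEA19 (-0.35, SE 0.12; 0.16 with spike scaling), the dehydrin Dhn1 (0.26, SE 0.18; 0.76 with spike scaling, where it passed at adjusted p = 0.0124) or RAB16D (0.39, SE 0.51). VP1 did pass as lower without gif1 replicate 2 (-0.99, limma adjusted p = 0.0243), with array weights (0.0497) and with the replicate block (0.0182). For the list, camera gave adjusted p = 0.00031, and adjusted p = 0.263 with an estimated correlation. The storage list lay at -0.62 and the ribosomal RNA probe sets at -1.06 on these arrays.

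Genes of cell division and of the cell wall leaned upward. In the cell cycle and DNA replication list 4 of 33 measured members rose, none fell and 29 did not pass, and 7 rose when adjusted over the list alone. The clamp loader subunit RFC5 differed by 0.98 (SE 0.17), replication protein RPA3 by 0.75 (SE 0.13) and histone H2B.5 by 0.66 (SE 0.12). MCM2, a subunit of the replicative helicase, went from 511 ± 226 to 1038 ± 227 (1.07, SE 0.29), but lost its call without any single array but wild-type replicate 1 (adjusted p up to 0.141), and stood at 0.71 without wild-type replicate 3. Its mean was 0.31, with camera adjusted p = 0.0227, and adjusted p = 0.495 with an estimated correlation. In the cell wall list 7 of 47 rose, 2 fell and 38 did not pass, against 10 and 2 when adjusted over the list alone. The secondary-wall cellulose synthases CESA4 (1.44, SE 0.23) and CESA7 (1.16, SE 0.21) rose, as did EXPB9, while the expansin EXPA5 fell (-1.25, SE 0.16). The mean of the wall list was 0.30, with camera adjusted p = 0.0227, and adjusted p = 0.495 with an estimated correlation. Spike scaling ended both calls (adjusted p = 0.0973) with larger means (0.80 and 0.79), leaving out wild-type replicate 2 or 3 ended both with means of 0.22 to 0.27, and the photosynthesis markers (0.86) rose on the same arrays.

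**Figure D2:**
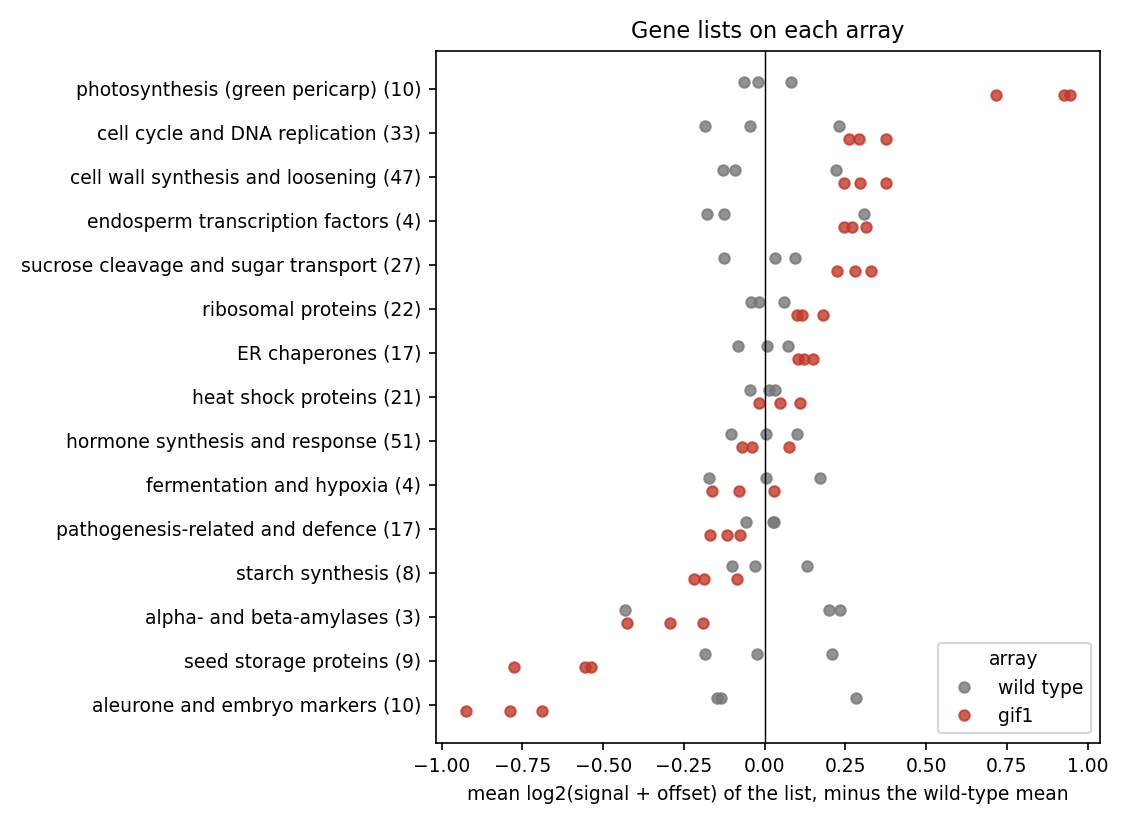
Mean log2(signal + offset) of each gene list on each array, minus the mean of the 3 wild-type arrays, with wild type in grey and gif1 in red; the number of measured members is in brackets. The photosynthesis list lay higher on all gif1 arrays (mean difference 0.86), and the storage (-0.62) and aleurone and embryo (-0.80) lists lay lower. Rescaling to the hybridization spikes or centring on the median moves the starch, defence, hormone, amylase and fermentation means above 0.

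Among 27 genes of sucrose cleavage and sugar transport, 4 rose and 2 fell, or 5 and 2 when adjusted over the list alone. Besides GIF1, sucrose synthase SUS4 fell (-0.81, SE 0.19; -0.30 and not passing with spike scaling). A second cell-wall invertase, CIN1, rose from 377 ± 111 to 915 ± 160 (1.27, SE 0.23), as did the transporters SWEET2B (1.47, SE 0.23) and SWEET5 (2.48, SE 0.60) and the fructokinase FRK1 (0.63, SE 0.16). Leaving out any 1 gif1 array ended the calls of SUS4 (adjusted p up to 0.0982) and FRK1 (up to 0.128), leaving out wild-type replicate 1 or 3 that of FRK1 (0.0503 and 0.0562), and single arrays also ended that of SWEET5 (up to 0.0999). Without single gif1 arrays the differences ran from -0.88 to -0.68 for SUS4 and from 0.53 to 0.72 for FRK1. The endosperm transporter SWEET11 read 35728 and 36228 (0.03, SE 0.11) and did not pass, though it did as a rise with median centring (0.36, adjusted p = 0.0375) and spike scaling (0.54, adjusted p = 0.00664). The list's mean was 0.28 and camera gave adjusted p = 0.220. The photosynthesis markers (0.86) were higher and the poly-A controls (-2.24) lower on the same arrays.

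The other lists did not pass as sets. Among 21 heat shock proteins 5 rose and 3 fell (7 and 5 when adjusted over the list alone), with HSP17.4 at 0.91 (SE 0.18), HSP17.9B at 0.71 (SE 0.14), HSP81-1 at 0.46 (SE 0.12; -0.23 in its other probe set, not passing) and CLPB1 at -0.84 (SE 0.18). That list's mean was 0.05 and its test pointed up, but its median was -0.03 (adjusted p = 0.681). Of 17 pathogenesis-related and defence genes 3 rose and 3 fell (4 and 5 when adjusted over the list alone), including Rcb4 (1.07, SE 0.19), the chitinases Cht11 (0.91, SE 0.22) and Cht1 (-0.72, SE 0.15), and Chib3H-h (-0.89, SE 0.21); the mean was -0.12 and adjusted p = 0.531. Of 51 hormone genes 3 rose and 3 fell (3 and 3 when adjusted over the list alone). The response regulators RR9 (0.82, SE 0.17) and RR6 (0.83, SE 0.20) rose, and GH3.4, which conjugates auxin (-0.87, SE 0.14), and IAA18 (-0.60, SE 0.16) fell, with a mean of -0.01 and adjusted p = 0.531. Leaving out some single array ended the calls of HSP81-1 (adjusted p up to 0.113), CLPB1 (0.0631), Cht11 (0.101), Cht1 (0.0612), Chib3H-h (0.0864), RR9 (0.0593), RR6 (0.0908) and IAA18 (0.116). Median centring and spike scaling turned the defence mean to 0.22 and 0.36 and the hormone mean to 0.33 and 0.47.

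Of 22 ribosomal protein genes 3 rose and 1 fell (4 and 1 when adjusted over the list alone). By their brightest probe sets RPL18 (0.79, SE 0.16), RPL27 (0.69, SE 0.20) and RPS3A (0.39, SE 0.11) rose and RPS21 fell (-0.36, SE 0.11; 0.00 after quantile normalization and 0.15 with spike scaling). No other probe set of the last 3 passed: those of RPL27 stood at 0.16 and -0.09, of RPS3A at 0.17, 0.25 and -0.41 and of RPS21 at -1.08 and -0.22. The list's mean was 0.13 with adjusted p = 0.242, and it passed upward after quantile normalization (0.0240), median centring (0.00603) and spike scaling (0.00273). Of 17 ER chaperone genes CRT1 rose (0.63, SE 0.12), and 4 rose when adjusted over the list alone; PDIL2-3 (0.35, SE 0.11), PDIL2-2 (0.42, SE 0.13) and PDIL2-1 (0.32, SE 0.11) did not pass over all probe sets. That mean was 0.12 with adjusted p = 0.242, which became 0.0483 with median centring. Of 4 endosperm transcription factors MADS6 rose (0.54, SE 0.13), also when adjusted over the list alone, while RSR1 (0.42, SE 0.40), NFYB1 (0.08, SE 0.11) and MADS29 (0.07, SE 0.13) did not pass; the mean was 0.28 and adjusted p = 0.291. None of 3 amylases passed (AMY2A -0.85, SE 0.27; AMY3E 0.05, SE 0.13; AMY3D -0.12, SE 0.61), though 1 was lower when adjusted over the list alone, and the mean was -0.30 with adjusted p = 0.506. None of 4 fermentation and hypoxia genes passed, also when adjusted over the list alone: NSHB2 (0.35, SE 0.20), NSHB1 (-0.46, SE 0.42; 1.61 in another probe set, which passed at adjusted p = 0.0208), Adh2 (-0.11, SE 0.12) and PDC2 (-0.07, SE 0.10; 0.43 with spike scaling, where it passed at adjusted p = 0.0174) had a mean of -0.07 and adjusted p = 0.681. Leaving out some single array ended the calls of RPL27 (adjusted p up to 0.145), RPS3A (0.132), RPS21 (0.158) and MADS6 (0.103). The amylase and fermentation means turned to 0.03 and 0.26 with median centring.

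Over all 15 lists, 5 passed with camera's preset correlation of 0.01 and 0 with an estimated correlation, where the lowest adjusted p was 0.263 and 2 lists lay under an unadjusted p of 0.05. The fry test, which asks whether a set's genes move on balance one way and does not compare them with other genes, passed 3 lists: photosynthesis (adjusted p = 0.00902), aleurone and embryo (0.0217) and storage (0.0412).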

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

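The scaling to hybridization spikes was chosen only after the results were seen; the other alternatives were planned. GIF1 kept its direction and its call under all 18 alternatives, with log2 differences from -1.95 to -1.29 (-1.95 to -1.52 leaving out single arrays) and adjusted p-values up to 0.0401. The arrays' signal limits what dim probe sets can show, and counts moved with the filter: 1122 lower without it, and 675 of at least 2-fold with the stricter one, which tests fewer probe sets. Without the variance trend 368 were higher, 416 lower and 620 at least 2-fold. Median centring gave 5817 higher, 613 lower and 1952 at least 2-fold, and spike scaling 9810, 463 and 3086, by construction since both raise the gif1 arrays. Of 74 called named genes 36 kept their call without the trend, 65 with median centring, 68 with quantile normalization, 67 without the filter and 63 of 73 with spike scaling, where 7 uncalled genes gained a call in their direction and PDC2 in the opposite one (adjusted p = 0.0174). Leaving out gif1 replicate 3 kept 58 of 74, gif1 replicate 1 59 of 73 and gif1 replicate 2 62 of 73, against 63 of 73, 65 of 73 and 70 of 73 without wild-type replicates 2, 3 and 1. Without some single array 24 of the 74 lost their call, 10 of them among the largest changes and the others MCM2, HSP81-1, CLPB1, Cht1, Cht11, Chib3H-h, RR6, RR9, IAA18, MADS6, RPL27, RPS3A, RPS21 and Wx (adjusted p up to 0.158, for RPS21 without gif1 replicate 1).

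Leaving out single arrays gave 722 to 2284 higher, 703 to 1987 lower and 835 to 1663 at least 2-fold, each lowest without gif1 replicate 3. Counts moved by over 1.5 times without gif1 replicate 1 (740 higher, 832 lower), without gif1 replicate 2 (869, 909), without gif1 replicate 3 (722, 703; 835 at least 2-fold), and, for lower calls, without wild-type replicate 2 (1124) or 3 (1037). The lists that passed ranged from 3 (without wild-type replicate 3) to 6. Adjusted p-values ranged from 0.0031 to 0.0870 for cell cycle (lost without wild-type replicate 2, 0.0870, or 3, 0.0633, or gif1 replicate 3, 0.0547), from 0.0018 to 0.129 for cell wall (lost without wild-type replicate 2, 0.129, or 3, 0.0513), and from 0.0378 to 0.174 for starch (gained without wild-type replicate 2, 0.0378, or gif1 replicate 2, 0.0411). They ranged from 1.52e-08 to 3.18e-06 for storage, 1.74e-08 to 2.03e-06 for photosynthesis and 4.78e-05 to 0.00138 for aleurone and embryo. The remaining lists did not pass without any single array: ER chaperones 0.148 to 0.581, amylases 0.366 to 0.608, endosperm factors 0.148 to 0.470, hormone 0.360 to 0.771, defence 0.473 to 0.776, ribosomal 0.141 to 0.545, sucrose 0.113 to 0.470. The test's direction reversed for fermentation (0.509 to 0.812; reversed at 0.687 without wild-type replicate 1, 0.509 without wild-type replicate 3, and 0.341 with spike scaling) and for heat shock (0.509 to 0.952; reversed at 0.952 without gif1 replicate 3 and 0.899 with the mean of all probe sets).

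With an estimated correlation 0 lists passed: adjusted p was 0.263 for aleurone and embryo and for photosynthesis, 0.495 for cell cycle and cell wall, and 0.455 for storage. Quantile normalization lost storage (0.183) and gained ribosomal proteins (0.0240), which median centring (0.00603) and spike scaling (0.00273) gained too. Median centring gained ER chaperones (0.0483), cell wall was lost without the filter (0.0834) and with spike scaling (0.0973), as was cell cycle (0.0973), and starch was gained with the stricter filter (0.0350) and the mean of all probe sets (0.0483). The cause was not tested.

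Log2 differences of named genes changed sign as follows. Quantile normalization gave AMY3D 0.19, RPS21 0.00206, BEI 0.10, PPDKB 0.0132 and AGPS2 0.02. Median centring gave AMY3D 0.22, Adh2 0.23, PDC2 0.26, PPDKB 0.0904 and AGPS2 0.13, and array weights AMY3D 0.0723. Spike scaling gave AMY3D 0.28, Adh2 0.40, PDC2 0.43, RPS21 0.15, Wx 0.0325, BEI 0.15, PPDKB 0.26 and AGPS2 0.31. Left-out arrays took AMY3E from -0.0609 (without gif1 replicate 2; -0.0433 without wild-type replicate 1) to 0.119, MADS29 from -0.0125 (without gif1 replicate 1) to 0.149 and NFYB1 from -0.00463 (without gif1 replicate 2) to 0.141. Of these genes only RPS21 and Wx had passed as reported. Of 23 genes and probe sets named after their values were seen, 17 had passed, and 8 of these lost the call without some single array: 9 kept it without gif1 replicate 3, 10 without gif1 replicate 2 and 11 without gif1 replicate 1. Of the 17, 5 kept it without the trend, 15 with median centring, 16 with quantile normalization and 12 with spike scaling. CAB2R turned to 0.0504 with quantile normalization, 0.0850 with median centring and 0.26 with spike scaling, and LEA19 to 0.16 with the last. Left-out arrays took RAB16D from -0.174 (without wild-type replicate 1) to 0.919 and SWEET11 from -0.0719 (without wild-type replicate 2) to 0.113.

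The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.034, 0.022 and -0.047, and 1 sample of 6 correlated best with its own number. The replicate block gave 1436 higher and 1394 lower, ended the calls of IAA18 (0.0505) and RPS21 (0.0638), gained AMY2A (0.0311), and, among genes named after their values were seen, ended those of Hox19 (0.0559) and OsPP2C30 (0.0556) and gained VP1 (0.0182). It changed no other call among the lists and the named genes run.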

Other observations

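The family and neighbourhood tests and all tests of an explanation below, and the genes named here, were chosen only after the result was seen; the counts of other splits were planned. Gene symbols were grouped by their letters into 48 families with at least 8 measured genes. With camera 0 passed (7 at an unadjusted p under 0.05), and a Fisher's exact test added after that, which treats genes as independent, found 1. In the family of symbols with the stem PP, mostly type 2C protein phosphatases, 13 of 57 genes fell and 1 rose: 22.8% fell, against 6.52% of 2194 named genes (exact adjusted p = 0.00432; camera adjusted p = 0.155, and adjusted p = 0.805 with an estimated correlation). The phosphatases OsPP2C08 (-1.17, SE 0.18), OsPP2C27 (-0.99, SE 0.18), OsPP2C09 (-0.87, SE 0.17) and OsPP2C30 (-0.63, SE 0.18) were among those that fell. The direction rests on the scaling. With quantile normalization 12 fell and 1 rose, with median centring 7 fell and 11 rose, and with spike scaling 3 fell and 18 rose. OsPP2C27, OsPP2C09 and OsPP2C30 no longer passed with spike scaling. The family's mean stayed below that of other named genes under each scaling. It was -0.21 against 0.07 as reported and -0.18 against 0.11 with quantile normalization. Median centring gave 0.13 against 0.41, and spike scaling 0.32 against 0.57. The unadjusted Fisher's exact p for falls was 8.04e-05 with quantile normalization, 0.000177 with median centring and 0.0576 with spike scaling. OsPP2C30 also lost its call without any single array but wild-type replicate 1 (adjusted p up to 0.138).

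Storage transcripts were lower and photosynthesis transcripts higher in gif1. A smaller share of starchy endosperm alone would raise the markers of the other tissues alike, but photosynthesis minus aleurone and embryo markers was 1.66 (SE 0.179). That gap cannot decide the question. Aleurone is itself part of the endosperm, so a smaller share of endosperm and embryo together would lower these markers too. Many of them are also induced by abscisic acid and may move for other reasons. A smaller endosperm share and a change within the pericarp both stay open. A scale that depends on signal would move genes of like brightness as far: the photosynthesis list lay 0.82 (SE 0.0882) above its 50 named genes of like signal, which argues against that for the rise. For storage it cannot be told apart: the list lay -0.26 (SE 0.0842) from 18 named genes of like signal, 88.9% of them lower. Their mean was -0.37, counting a gene again for each storage member it lay near. Only the storage and photosynthesis lists were kept out of these genes, so bright starch synthesis genes could be among them. Their fall need not come from scale alone. The gap was -0.13 (SE 0.0622) without RAG1. Quantile normalization, which evens out such a scale, took the storage mean from -0.62 to -0.19 and ended the call. It makes the highest ranks alike on every array, so it would also shrink a real fall of the brightest genes. That loss therefore cannot decide between scale and a real fall. A direct effect of the lesion on storage gene expression was not tested, and 3 further comparisons of this kind were run and are not weighed: storage minus all genes as bright (-0.34, SE 0.0819), starch minus storage (0.46, SE 0.0716), and poly-A minus hybridization controls (-1.73).

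Calls were frequent near GIF1. Among the 50 tested genes nearest to it in gene order, 12 were called (5 rose, 7 fell; 24%), against 13.6% of all genes and a median of 7 in windows of that size, which put GIF1 at percentile 96.8. A hypothesis is that the mutant differs from Zhonghua11 at linked sites near the lesion. These arrays cannot separate it from local effects of the lesion itself or from chance, since the 95th percentile of windows was already 11 calls. The excess depends on the window, with 5 calls among the nearest 10 genes (percentile 99.2), 7 among 20 (98.6), 18 among 100 (86.9) and 29 among 200 (63.9). Within the nearest 10, LOC4335788 (2.11, SE 0.56), LOC4335782 (1.31, SE 0.25) and LOC4335799 (0.55, SE 0.11) rose and LOC4335798 (-1.58, SE 0.33) and LOC4335793 (-1.21, SE 0.21) fell, though LOC4335788 lost its call without any 1 gif1 array (adjusted p up to 0.131) and stood at 1.26 without wild-type replicate 3, and LOC4335798 lost it without gif1 replicate 3 (0.0516).

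RAB16A, RAB16B, RAB16C, rab25, Emp1 and OsPM19L1 transcripts, which abscisic acid is known to induce, were lower in gif1, while RAB16D (0.39), Dhn1 (0.26) and LEA19 (-0.35), also in the aleurone and embryo list, did not pass. The lower genes were picked because they fell. RAB16D, Dhn1 and LEA19 may respond to abscisic acid too, so the fall may not hold for all such genes. Clade A type 2C phosphatases, also induced by abscisic acid, were listed from memory after 2 of them had been seen to fall. The 5 measured of 11 listed lay -0.57 from the 45 others, but the 3 not seen beforehand lay -0.36 from them (exact permutation p = 0.252), so whether a weaker abscisic acid response plays a part stays open. Slower development of the caryopsis could also lower late markers, and it cannot be told apart here. The cell cycle list, which should then rise, had a mean of 0.31 and camera adjusted p = 0.0227 at the preset correlation of 0.01. With an estimated correlation its adjusted p was 0.495, but 0 of the 15 lists passed at that setting, so that value cannot decide. Slower development was not weighed for the storage and photosynthesis lists.

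The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1709 probe sets higher, 1716 lower and 1280 at least 2-fold, and the highest of the other splits gave 0 in each case. Every other split mixes the genotypes within its groups, so the genotype difference itself widens their spread. Few calls would then be made there, so those splits do not show what arrays without a genotype difference would give. For each of these counts 1 of 10 splits, the real one, gave as many. For gene lists the real split passed 5, the highest other 3, and again 1 of 10 gave as many.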
